A study of Mus musculus with 24 samples.

How the data were processed

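Gene expression was measured by bulk RNA-seq in hippocampus and cortex, in 24 libraries. Per the labels' protocols, RNA was extracted with an RNeasy kit and libraries were made with the Illumina Stranded mRNA Prep, which selects polyadenylated RNA. Per the submitters' processing notes, transcripts were quantified with kallisto 0.45.0 and the GRCm38 build. The table the authors deposited holds log2 values per Ensembl gene. Its lowest value is 0 and its highest 12.5, as a log2 of a quantity plus 1 gives, and 39.3% of its values are 0. The offset inside the logarithm, the step from transcripts to genes and any filter were not given in the sources used here. With an offset of 1 assumed, the sum of the quantity underneath differs between libraries, so it is like TPM but not scaled to a fixed sum. A log2 scale with an offset understates changes of genes with low values, and a value of 0 can be a failed estimate. Depth per library is unknown because the values keep no read counts, so no counting interval is given, and precision is given by the spread between libraries. The authors' sample sheet gives the animal, the tissue, a group name and the RNA concentration, and these other columns were used only as checks.

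Of 52143 lines in the table, 596 repeated an identifier and were kept once, which left 51547 genes, and 51250 identifiers were matched to a gene name. All 24 sample columns were used. Groups were taken from the labels. The sample sheet gives another group to 12 of the 24 libraries, and exchanging the names of both 5xFAD groups without WT donor cells was run as an alternative. The labels do not say which libraries share an animal, so libraries were treated as independent. With the animal of the sample sheet as a random block the consensus correlation was -0.030.

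The values were tested as deposited with limma-trend (limma 3.58.1, R 4.3.3) in 1 fit per tissue of 12 libraries and 5 groups, with 7 residual degrees of freedom. Genes with a value above 0 in at least 2 libraries were tested, 36215 in hippocampus and 35965 in cortex, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The design written before the data were examined named a count-based test first and this test for log2 values, and the unit decided. An exact test of 3 libraries against 3 cannot go below p = 0.1, so p-values rest on the spread that limma shares between genes and groups. Adjusted p-values in the text are from limma, or from its camera function for gene lists. In each tissue 5 comparisons were made, which are called the model comparison (5xFAD against WT), the WT donor comparison (5xFAD + WT HSPC against 5xFAD), the donor genotype comparison (5xFAD + WT HSPC against 5xFAD + 5xFAD HSPC), the 5xFAD donor comparison (5xFAD + 5xFAD HSPC against 5xFAD) and the comparison with healthy mice (5xFAD + WT HSPC against WT). The difference of an effect between tissues was tested in 1 fit of 24 libraries and 10 groups with 14 residual degrees of freedom. The single WT + WT HSPC library of each tissue was its own group and entered no comparison.

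Gene lists of cell types and pathways, 37 in all, were written before the data were examined. Of these, 32 were tested with camera, with a preset correlation of 0.01 between genes and adjustment over the 32 lists of a comparison, and again with an estimated correlation. Camera tests whether a list moved relative to all other genes, so its direction can differ from the sign of a list's mean. Members were also adjusted over their list alone. Where the median difference of genes with a mean log2 of at least 1 was further than 0.1 from 0, changes are given less that median. Camera does not test these values. Genes were named by a rule fixed in advance: 13 genes of interest, called genes with a name of their own whose groups did not overlap, up to 10 per direction and largest first, and the 2 to 4 members with the smallest p of each list described. Values of some of these genes are not reported here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

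The tests were checked on simulated data in which 100 genes were changed by a log2 of 1 and 100 by a log2 of 2. In the model comparison the fit found 72 and 90 of them in hippocampus (8 false calls) and 4 and 69 in cortex (3). In the WT donor comparison it found 72 and 92 in hippocampus (10) and 7 and 82 in cortex (5). Of 200 lists with no change, 4 to 8 had p under 0.05 per comparison, and all 50 lists shifted by 0.5 were found. Whether this holds for lists of correlated genes was not tested.

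Alternatives fixed before the data were examined were limma without trend, quantile normalization, no filter, only the 2 groups compared, both tissues in 1 fit, sex read from Xist and Y-linked genes as a covariate, all 3 WT libraries as the WT group, an estimated correlation, other sets of genes from the model comparison, and each library left out in turn. For gene lists, only quantile normalization, the estimated correlation and the libraries left out were fixed then, and the others were added after seeing the data. Other alternatives chosen after seeing the data were a filter at a mean log2 of 1, median-centred libraries, the exchanged group names, the animal as a block, the Thy1 level as a covariate, and leaving out libraries with Thy1 against the label or cortex libraries with AY036118 of at least 9.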

Results

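Bulk RNA-seq was read in the hippocampus and cortex of mice 4 months after transplantation of haematopoietic stem and progenitor cells (HSPCs), the bone marrow cells that give rise to blood and immune cells, macrophages among them. The 5xFAD mouse is a model of Alzheimer's disease that carries transgenes under the Thy1 promoter, mutant human APP among them. Of the 24 libraries, 12 came from each tissue. In each tissue 3 were labelled 5xFAD without transplant, 3 were labelled 5xFAD + 5xFAD HSPC, 3 were labelled 5xFAD + WT HSPC, 2 were labelled WT without transplant and 1 was labelled WT + WT HSPC. The authors' sample sheet traces the libraries to 12 animals, each with both tissues. Expression was given per gene as a log2 value, so the read depth is unknown. Between 30009 and 33630 genes had a value above 0 in a library. The 20 pairs of libraries from 1 group differed by a root mean square of 0.372 to 0.958 log2 per gene, and none was a copy of another. Differences given here are in log2 units between groups as labelled, with the standard error (SE) of the limma fit, and the tests of gene lists used a preset correlation of 0.01 between genes unless an estimated correlation is named.

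The genes that read the transgenes were examined first, as a check of the genotype labels. Thy1 (ENSMUSG00000032011, GRCm38 chromosome 9, 44043384 to 44048579) drives the transgenes through its promoter. In cortex, Thy1 was 6.37 and 6.36 in the libraries labelled WT and 5.69 in the library labelled WT + WT HSPC. It was 6.12, 7.70 and 7.72 in cortex libraries 1 to 3 labelled 5xFAD, 7.44, 7.78 and 7.55 in those labelled 5xFAD + 5xFAD HSPC, and 6.20, 6.04 and 6.93 in those labelled 5xFAD + WT HSPC. In hippocampus, Thy1 was 7.88 and 7.93 in the libraries labelled WT and 6.13 in the library labelled WT + WT HSPC. It was 6.20, 7.90 and 7.71 in hippocampus libraries 1 to 3 labelled 5xFAD, 7.85, 6.25 and 7.90 in those labelled 5xFAD + 5xFAD HSPC, and 6.08, 6.22 and 7.90 in those labelled 5xFAD + WT HSPC. App (ENSMUSG00000022892, chromosome 16, 84949685 to 85173766) was 6.90 and 6.88 in the hippocampus libraries labelled WT and 6.19, 7.005 and 6.88 in those labelled 5xFAD. It was 6.85, 6.10 and 6.93 in those labelled 5xFAD + 5xFAD HSPC, and 6.12, 6.26 and 6.96 in those labelled 5xFAD + WT HSPC. With the median deviation of each library subtracted and 7 taken as the border, a value chosen after the levels were seen, Thy1 went against the labelled genotype in 9 of 24 libraries. These were both hippocampus libraries labelled WT, libraries 1 and 2 labelled 5xFAD + WT HSPC in both tissues, library 1 labelled 5xFAD in both tissues, and hippocampus library 2 labelled 5xFAD + 5xFAD HSPC. Every direction in the comparisons is therefore one between labels.

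**Figure D1:**
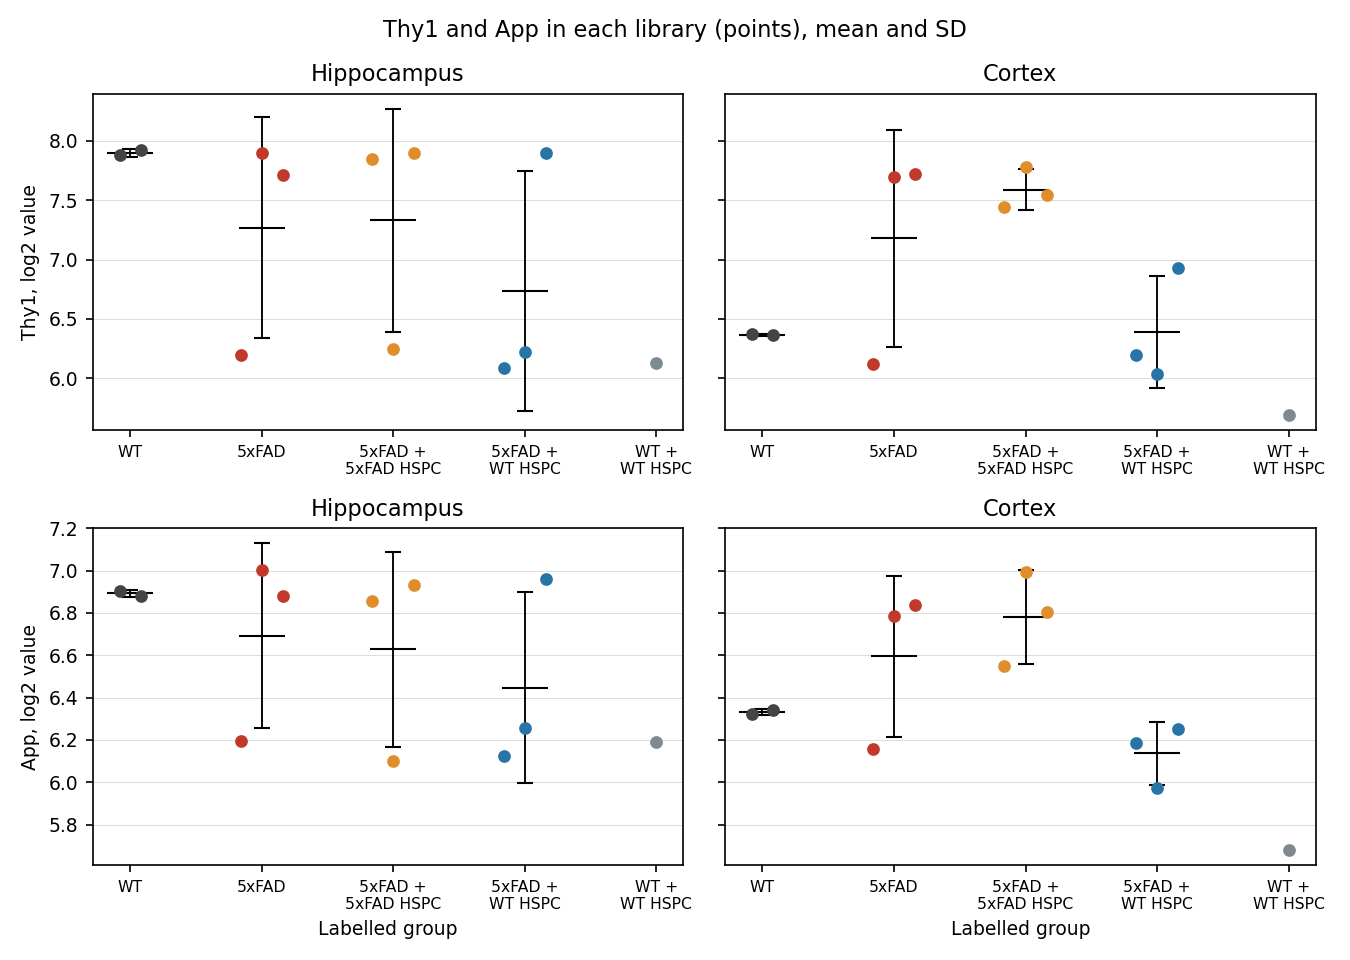
Log2 expression (y axis) of Thy1 and App in each of the 24 libraries (points), by labelled group (x axis) and tissue, with the mean (line) and SD (bar) of each group. The hippocampus libraries labelled WT lay at 7.88 and 7.93 for Thy1, those in cortex at 6.37 and 6.36.

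Xist, expressed from the inactive X chromosome of females, was set against the Y-linked Ddx3y. Xist lay above Ddx3y in 7 libraries, and in 3 of the 12 animals of the sample sheet the tissues differed. Xist was 5.11 in hippocampus against 0.24 in cortex for library 2 labelled 5xFAD + 5xFAD HSPC, 0.39 against 4.92 for WT library 1 and 0.50 against 4.89 for WT library 2. The sample sheet also gave 12 of the 24 libraries another group than their labels, exchanging 5xFAD with 5xFAD + 5xFAD HSPC in both tissues, and the labels were kept. With the names of the sheet, the comparisons of libraries labelled 5xFAD + WT HSPC with 5xFAD and with 5xFAD + 5xFAD HSPC would take each other's values. In cortex, 4 libraries stood apart by AY036118, a transcript made of ribosomal RNA sequence. It was 9.46 and 9.68 in libraries 2 and 3 labelled 5xFAD + WT HSPC, 9.66 in library 1 labelled 5xFAD + 5xFAD HSPC and 10.18 in the library labelled WT + WT HSPC. Their median over expressed genes deviated by -0.35, -0.48, -0.69 and -0.65 from the mean of all libraries.

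**Figure D2:**
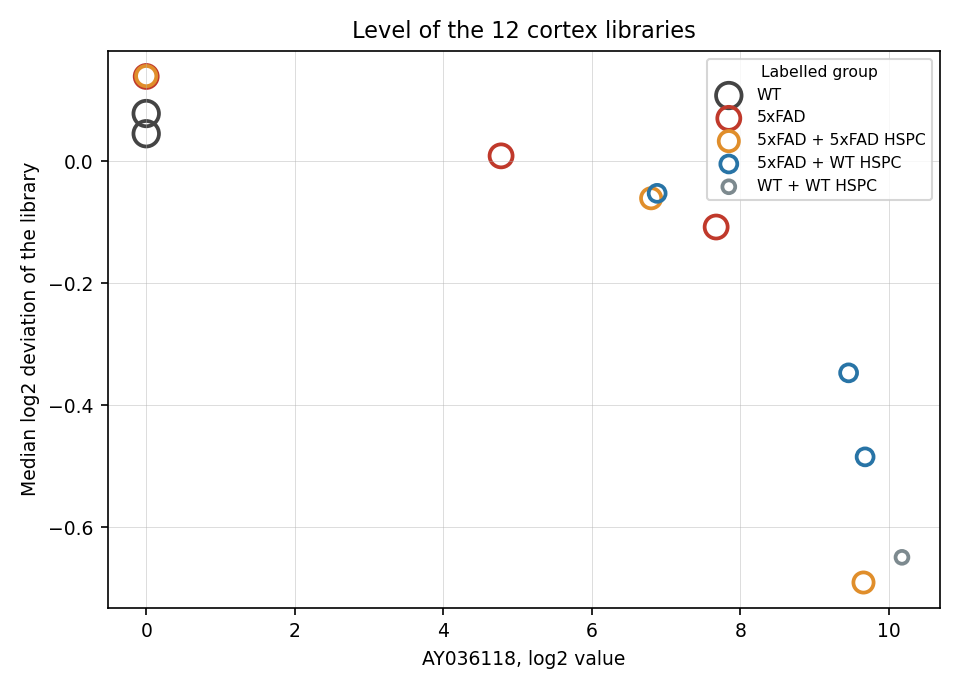
Log2 value of the ribosomal-RNA-derived AY036118 (x axis) against the median log2 deviation of expressed genes from the mean of all libraries (y axis) in the 12 cortex libraries, 1 ring per library, coloured by labelled group. The 4 libraries at AY036118 values of 9.46 to 10.18 had median deviations of -0.35 to -0.69.

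The libraries labelled 5xFAD and WT, both without transplant, were compared to ask how the model differs from healthy mice. In hippocampus, myelin genes rose in the libraries labelled 5xFAD, with all 15 members of the myelinating oligodendrocyte list higher by a mean of 0.59 (adjusted p = 2.9e-11, and adjusted p = 0.88 with an estimated correlation). Mag, an adhesion protein of myelin, was 5.00 ± 0.16 (SD, n = 3) in the libraries labelled 5xFAD and 4.31 ± 0.05 (SD, n = 2) in those labelled WT, and Cnp, a myelin enzyme, was 4.64 ± 0.16 against 4.00 ± 0.09. Ugt8a, which makes myelin galactolipids, differed by 0.64 (SE 0.16) and Mal by 0.61 (SE 0.16). The oligodendrocyte precursor list rose as well (mean 0.21, 10 of 12 members higher, adjusted p = 0.030, and adjusted p = 0.88 with an estimated correlation). Enpp6 was at 0.49 (SE 0.10) and Sox10 at 0.39 (SE 0.12). Genes of the choroid plexus, which makes cerebrospinal fluid, and of the ependyma were higher in all 15 members (mean 1.40, adjusted p = 8.7e-08, and adjusted p = 0.88 with an estimated correlation). Tmem212 was at 0.62 (SE 0.13), the ciliary regulator Foxj1 at 0.83 (SE 0.22) and Otx2 at 1.90 (SE 0.64). Their list mean was 3.19, 1.77 and 3.41 in libraries 1 to 3 labelled 5xFAD and 1.37 and 1.42 in those labelled WT. Markers of striatum and thalamus, regions near the hippocampus, had a list mean of 3.61, 2.28 and 2.16 in libraries 1 to 3 labelled 5xFAD and of 2.11 and 2.10 in those labelled WT. The myelin mean was 4.39, 4.44 and 4.16 against 3.75 and 3.74, and without library 1 labelled 5xFAD it differed by 0.56 (adjusted p = 1.4e-08).

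Microglial and inflammatory genes went the other way in hippocampus. The disease-associated microglia list, genes that microglia raise near amyloid plaques, fell (mean -0.35, 25 of 30 members lower, adjusted p = 3.4e-04, and adjusted p = 0.88 with an estimated correlation). Spp1, osteopontin, was at -0.87 (SE 0.43), the chemokine Ccl3 at -1.21 (SE 0.89) and Igf1 at -0.40 (SE 0.32), while Lgals3 was at 0.44 (SE 0.34). The list mean was 2.26, 3.16 and 3.15 in libraries 1 to 3 labelled 5xFAD and 3.21 in both labelled WT, the libraries whose Thy1 went against the label. The type I interferon response list (mean -0.14, 15 of 20 lower), the inflammatory cytokine and chemokine list (mean -0.22, 12 of 16 lower), the MHC class I list (mean -0.13, 11 of 15 lower) and the cholesterol synthesis list (mean -0.12, 13 of 18 lower) fell. They had adjusted p = 7.3e-04 to 0.031, and adjusted p = 0.88 with an estimated correlation in each. Rsad2 was at -0.30 (SE 0.12), Il1a at -0.35 (SE 0.16), the NF-kB inhibitor Nfkbia at 0.55 (SE 0.14) and Tap2 at -0.22 (SE 0.19). Msmo1, an enzyme of cholesterol synthesis, was at -0.31 (SE 0.11). With the group names of the sample sheet the interferon response and MHC class I lists turned to 0.11 and 0.11 (adjusted p = 0.97 and 0.71), and the disease-associated microglia (-0.12, adjusted p = 0.24), inflammatory (adjusted p = 0.79) and oxidative phosphorylation calls (0.050, adjusted p = 0.52) were lost. The test of the inflammatory list turned, at a mean of -0.036, among genes with a mean log2 of at least 1 (adjusted p = 0.79). Oxidative phosphorylation genes rose by a mean of 0.10 (21 of 22 higher, adjusted p = 0.020, and adjusted p = 0.88 with an estimated correlation). Ndufb8 of complex I was at 0.25 (SE 0.06). Adjusted over the list alone, 13 myelin, 3 choroid plexus and 1 precursor genes passed, and over all genes no member of any list did. Over 36215 genes limma called 6 higher and 8 lower, all short or unnamed transcripts, and 3542 had an unadjusted p under 0.05 where 1811 were expected by chance. The 5S ribosomal RNA gene n-R5s216 (3.23 ± 0.39, SD, n = 3) and Rpl35-ps1 (0.93 ± 0.18) were listed at 0 in the libraries labelled WT. Traj44, a T cell receptor segment, and Mir207 were listed at 0 in those labelled 5xFAD. Apoe differed by -0.06 (SE 0.22), Trem2 by -0.48 (SE 0.69) and Cst7 by -1.19 (SE 1.26), and none of the 13 genes fixed in advance passed. Centring the libraries on their medians gave 3 higher and 7 lower genes. The disease-associated microglia call was lost without library 1 labelled 5xFAD (mean -0.05, adjusted p = 0.32) and with sex as a covariate. Without that library the precursor, cholesterol synthesis, interferon response, inflammatory, MHC class I and oxidative phosphorylation calls were lost too (adjusted p = 0.24 to 0.73), as they were without library 1 labelled WT (adjusted p = 0.062 to 0.27). No library labelled WT was left once those with Thy1 against the label were set aside.

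In cortex the same comparison gave more disease-associated microglia transcript in the libraries labelled 5xFAD. That list rose (mean 0.32, 24 of 30 higher, adjusted p = 4.7e-07, and adjusted p = 0.94 with an estimated correlation). The integrin Itgax was at 0.72 ± 0.57 (SD, n = 3) against 0.06 ± 0.06 (SD, n = 2), the lectin receptor Clec7a at 0.91 (SE 0.42), Cd52 at 1.05 (SE 0.39) and Lgals3, galectin 3, at 0.49 (SE 0.13). Per library the list mean was 2.02, 2.66 and 2.77 in libraries 1 to 3 labelled 5xFAD and 2.17 in both labelled WT. The difference was 0.55 without library 1 labelled 5xFAD (adjusted p = 1.1e-18) and 0.17 without library 3 labelled 5xFAD (adjusted p = 0.046). It was 0.70 with the group names of the sample sheet (adjusted p = 7.5e-39), and with the Thy1 level as a covariate the test turned at a mean of 0.017 (adjusted p = 0.76). Cst7, a cystatin of plaque-associated microglia, was 0.71, 2.82 and 3.14 against 0.55 and 0.90. The inflammatory cytokine and chemokine list rose by a mean of 0.15 (11 of 16 higher, adjusted p = 0.034, and adjusted p = 0.94 with an estimated correlation). Cxcl10 was at 0.36 (SE 0.18) and Ccl12 at 0.33 (SE 0.20). The call was lost without library 3 labelled 5xFAD (adjusted p = 0.13) or library 1 labelled WT (adjusted p = 0.34). All 15 choroid plexus and ependyma genes had a higher mean (mean 0.39, adjusted p = 9.1e-06, and adjusted p = 0.94 with an estimated correlation). Tmem212 was at 0.31 (SE 0.13) and Folr1 at 0.60 (SE 0.32). Immediate early genes, induced by neuronal activity, fell (mean -0.39, 16 of 17 lower, adjusted p = 2.3e-03, and adjusted p = 0.98 with an estimated correlation). Egr2 was at -0.92 (SE 0.41), Fos at -0.81 (SE 0.41) and Junb at -0.70 (SE 0.42), and the call was lost without library 1 labelled WT (adjusted p = 0.060). No member passed adjusted over the list alone or over all genes. Of 35965 genes limma called 3 higher and 22 lower, and 1067 had an unadjusted p under 0.05 where chance gives 1798. The microRNA gene Mir8114 was at 2.39 ± 0.54 (SD, n = 3) and listed at 0 in the libraries labelled WT. Mir7027 (2.92 ± 0.15, SD, n = 2, in those labelled WT), Mir1947 (2.36 ± 0.23), Mir7681 (2.10 ± 0.11), Mir6905 (2.06 ± 0.15) and the pseudogene Mpc1-ps (1.35 ± 0.27) were listed at 0 in those labelled 5xFAD. Quantile normalization gave 8 higher and 23 lower genes, and median-centred libraries 6 and 11. The disease-associated microglia list was at -0.15 with sex as a covariate (adjusted p = 0.29), since library 1 labelled 5xFAD and both labelled WT had Xist above Ddx3y. The choroid plexus call was lost without library 1 labelled 5xFAD (mean 0.13, adjusted p = 0.23) and with the group names of the sample sheet (-0.059, adjusted p = 0.14).

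The libraries labelled 5xFAD + WT HSPC were set against those labelled 5xFAD to ask what transplantation of healthy donor cells changed. In hippocampus, microglial, antigen presentation, myelin and choroid plexus genes fell, while excitatory neuron, synapse and immediate early genes rose. The disease-associated microglia list fell (mean -0.37, 28 of 30 lower, adjusted p = 2.1e-03, and adjusted p = 0.63 with an estimated correlation). Spp1 was at 1.16 ± 0.37 against 2.34 ± 0.28 (SD, n = 3 each), the tetraspanins Cd63 at -0.30 (SE 0.18) and Cd9 at -0.48 (SE 0.31), and Cybb at 0.25 (SE 0.16). Lysosome genes were lower in all 22 members (mean -0.25), homeostatic microglia genes in 15 of 18 (mean -0.21), MHC class II genes in 9 of 11 (mean -0.30) and MHC class I genes in 12 of 15 (mean -0.18). Interferon response genes fell in 19 of 20 (mean -0.17), reactive astrocyte genes in 17 of 20 (mean -0.16) and border-associated macrophage genes in 8 of 12 (mean -0.12). These 7 lists had adjusted p = 3.5e-04 to 0.044, and adjusted p = 0.63 with an estimated correlation in each. Lgmn was at -0.27 (SE 0.16), Ctsl at -0.26 (SE 0.17), the growth factor receptor Csf1r at -0.49 (SE 0.35), H2-Ab1 at -0.80 (SE 0.31) and the invariant chain Cd74 at -0.96 (SE 0.51). H2-D1 was at -0.51 (SE 0.33), Ifitm3 at -0.47 (SE 0.24), Steap4 at -0.31 (SE 0.15) and the scavenger receptor Cd163 at -0.32 (SE 0.13). Myelin genes fell in all 15 members (mean -0.28, adjusted p = 5.0e-07), as did choroid plexus and ependyma genes (mean -0.67, adjusted p = 6.1e-05), both at adjusted p = 0.63 with an estimated correlation. Ermn was at -0.37 (SE 0.13) and Otx2 at -1.07 (SE 0.58). The precursor (mean -0.14, adjusted p = 3.3e-03), fibroblast and meninges (mean -0.26, adjusted p = 2.3e-03) and neurogenesis and proliferation lists (mean -0.11, adjusted p = 0.044) fell too, again at adjusted p = 0.63 with an estimated correlation. Fmod was at -0.70 (SE 0.31) and Rrm2 at -0.35 (SE 0.12). Excitatory neuron genes rose (mean 0.17, 10 of 12 higher, adjusted p = 1.0e-04), together with synapse genes (mean 0.10, 20 of 23 higher, adjusted p = 1.1e-04) and immediate early genes (mean 0.10, 14 of 17 higher, adjusted p = 0.024). With an estimated correlation each had adjusted p = 0.63. Camkv was at 0.27 (SE 0.11), the scaffold Dlg4 at 0.15 (SE 0.07), the glutamate receptor Gria1 at 0.23 (SE 0.11) and Egr4 at 0.40 (SE 0.14). No member passed adjusted over the list alone or over all genes. limma called 4 higher and 2 lower genes (3 and 0 with median-centred libraries, 4 and 1 with quantile normalization) with 1790 genes at an unadjusted p under 0.05 and 1811 expected by chance. Rpl35-ps1 was listed at 0 in the libraries labelled 5xFAD + WT HSPC and was 0.93 ± 0.18 (SD, n = 3) in those labelled 5xFAD. The choroid plexus mean was 3.04, 1.70 and 1.62 in libraries 1 to 3 labelled 5xFAD + WT HSPC, and that of striatum and thalamus markers 2.31 ± 0.54 against 2.68 ± 0.80 (SD, n = 3 each). The choroid plexus difference was -1.13 without library 1 labelled 5xFAD + WT HSPC, -1.18 without library 2 labelled 5xFAD and -0.42 without library 3 labelled 5xFAD + WT HSPC. Its call was lost without library 2 labelled 5xFAD + WT HSPC (-0.46, adjusted p = 0.066) or library 3 labelled 5xFAD (-0.36, adjusted p = 0.14), when 2 and 4 lists passed. The synapse call was lost without the former (0.044, adjusted p = 0.066), and the lysosome and fibroblast calls without either (adjusted p = 0.066 to 0.50). Without the 3 libraries whose Thy1 went against the label, 1 list of 16 passed, and the disease-associated microglia mean was -0.19 (adjusted p = 0.25). It also missed the threshold without library 2 labelled 5xFAD + WT HSPC (-0.25, adjusted p = 0.18), library 2 labelled 5xFAD (-0.22, adjusted p = 0.12) or library 3 labelled 5xFAD (-0.22, adjusted p = 0.38), and was -0.61 without library 3 labelled 5xFAD + WT HSPC and -0.67 without library 1 labelled 5xFAD.

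In cortex, the median over expressed genes was -0.30 between the same groups, and 2 of the 3 libraries labelled 5xFAD + WT HSPC were rich in ribosomal RNA, so changes are given less that median. Microglial means lay below it, which camera did not test. Lysosome genes stood at -0.13 (22 of 22 below 0 before the median was taken off, adjusted p = 2.2e-06), disease-associated microglia genes at -0.17 (30 of 30, adjusted p = 7.9e-06), homeostatic microglia genes at -0.15 (18 of 18, adjusted p = 1.0e-05) and MHC class I genes at -0.08 (15 of 15, adjusted p = 2.5e-03). Each was at adjusted p = 0.93 with an estimated correlation. The protease Ctss stood at -0.44 (SE 0.26), Grn, progranulin, at -0.23 (SE 0.19) and Ctsd at -0.26 (SE 0.23). Csf1r was at -0.46 (SE 0.21), Siglech at -0.35 (SE 0.20) and the immunoproteasome subunit Psmb8 at -0.25 (SE 0.19). Myelin, interferon response and cholesterol synthesis genes also passed as lower (adjusted p = 0.013, 0.048 and 0.048, and 0.93 with an estimated correlation). Their means were -0.31, -0.33 and -0.34, or -0.01, -0.03 and -0.04 less the median. Choroid plexus and ependyma genes passed as higher (adjusted p = 4.4e-03, and 0.93 with an estimated correlation) at 0.33 less the median, where their mean was 0.03 and their median -0.04. Their list mean was 1.16, 1.81 and 1.83 in libraries 1 to 3 labelled 5xFAD + WT HSPC and 2.10, 1.35 and 1.27 in those labelled 5xFAD. No member passed adjusted over the list alone or over all genes, where limma called 4 higher and 2 lower (9 and 1 with median-centred libraries). In all 1789 genes had an unadjusted p under 0.05 where 1798 were expected by chance. Mir8114 was listed at 0 in the libraries labelled 5xFAD + WT HSPC and was 2.39 ± 0.54 (SD, n = 3) in those labelled 5xFAD. Quantile normalization ended the disease-associated microglia call (-0.18, adjusted p = 0.096) and leaving out library 3 labelled 5xFAD ended all 8 list calls. The choroid plexus call was also lost without library 2 or 3 labelled 5xFAD + WT HSPC (adjusted p = 0.20 and 0.50) or library 2 labelled 5xFAD (adjusted p = 0.31). The choroid plexus list turned to -0.41 without the libraries rich in ribosomal RNA.

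Libraries labelled 5xFAD + WT HSPC were set against 5xFAD + 5xFAD HSPC for the donor genotype. Their labels also name GFP in WT donor cells only and call the other arm mock. In cortex, microglial genes were lower with WT donors throughout the lists. All 30 disease-associated microglia genes were lower (mean -0.85, adjusted p = 9.3e-46, and 0.035 with an estimated correlation), and 21 of them fell adjusted over the list alone. Itgax was 0.17 ± 0.14 in the libraries labelled 5xFAD + WT HSPC and 1.47 ± 0.29 in those labelled 5xFAD + 5xFAD HSPC (SD, n = 3 each). Clec7a was 0.56 ± 0.47 against 2.23 ± 0.33, the chemokine Ccl4 was 0.07 ± 0.06 against 1.26 ± 0.32 and cathepsin Z, Ctsz, was 2.83 ± 0.13 against 3.73 ± 0.12. Complement genes, which tag synapses and debris for removal, fell in 13 of 13 members (mean -0.59, adjusted p = 2.5e-18, and 0.035 with an estimated correlation), 8 of them adjusted over the list alone. C1qa differed by -1.09 (SE 0.24), C1qb by -1.07 (SE 0.24), C1qc by -1.14 (SE 0.26) and C4b by -1.31 (SE 0.32). The inflammatory cytokine and chemokine list fell in 15 of 16 members (mean -0.39, adjusted p = 3.4e-10, and 0.025 with an estimated correlation), 4 of them adjusted over the list alone. Cxcl10 was at -0.80 (SE 0.16) and Ccl3 at -1.68 (SE 0.49), and the call was lost without library 1 labelled 5xFAD + 5xFAD HSPC (-0.40, adjusted p = 0.071). These 3 lists were the ones that also passed with an estimated correlation. With the group names of the sample sheet no list passed with an estimated correlation, and the disease-associated microglia mean was -0.47, or -0.17 less the median (adjusted p = 7.9e-06, and adjusted p = 0.93 with an estimated correlation). The complement (-0.37, adjusted p = 0.12) and inflammatory calls (-0.23, adjusted p = 0.60) were then lost. Lysosome genes (mean -0.60, 22 of 22 lower, 10 adjusted over the list alone) and homeostatic microglia genes (mean -0.57, 18 of 18 lower, 8 adjusted over the list alone) fell at adjusted p = 2.9e-30 and 7.8e-23. With an estimated correlation both had adjusted p = 0.073. Ctss was at -1.28 (SE 0.26), Csf1r at -1.07 (SE 0.21) and the fractalkine receptor Cx3cr1 at -0.78 (SE 0.20).

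Antigen presentation and astrocyte genes followed in cortex. MHC class I genes fell in 15 of 15 members (mean -0.52, 7 adjusted over the list alone, adjusted p = 8.8e-18, and 0.073 with an estimated correlation). Their activator Nlrc5 was at -0.72 (SE 0.16) and H2-D1 at -0.90 (SE 0.22). The MHC class II list (mean -0.42, 10 of 11 lower, 4 adjusted over the list alone), the interferon response list (mean -0.46, 20 of 20 lower) and the reactive astrocyte list (mean -0.34, 15 of 20 lower, 5 adjusted over the list alone) fell. They had adjusted p = 1.9e-11, 1.9e-17 and 1.9e-07, and 0.073, 0.081 and 0.081 with an estimated correlation. Cd74 was at -1.05 (SE 0.26), Ifit3 at -0.80 (SE 0.21), Ifitm3 at -0.76 (SE 0.24), Gfap at -1.45 (SE 0.34), Aspg at -1.05 (SE 0.18) and Vim at -0.60 (SE 0.14). The reactive astrocyte call was lost without library 1 labelled 5xFAD + 5xFAD HSPC (-0.39, adjusted p = 0.11). Smaller means came with the myelin (-0.27), cholesterol synthesis (-0.25), precursor (-0.24), pericyte (-0.18) and astrocyte (-0.16) lists, at adjusted p = 5.2e-07 to 0.032, and 0.40 to 0.88 with an estimated correlation. Cldn11 was at -0.46 (SE 0.17) and Aqp4 at -0.37 (SE 0.14). Without library 2 labelled 5xFAD + 5xFAD HSPC, among others, the pericyte and astrocyte calls were lost (adjusted p = 0.14 and 0.27). Choroid plexus and ependyma genes rose (mean 0.48, 12 of 15 higher, adjusted p = 2.3e-12, and 0.095 with an estimated correlation). Aqp1 was at 0.45 (SE 0.18) and Otx2 at 0.70 (SE 0.29). Red blood cell genes rose as well (mean 0.14, 7 of 8 higher, adjusted p = 3.9e-04, and adjusted p = 0.13 with an estimated correlation). Trem2, a lipid receptor of microglia, differed by -1.46 (SE 0.36), Cst7 by -2.33 (SE 0.63), Apoe by -0.39 (SE 0.18), P2ry12 by -0.39 (SE 0.17) and Tmem119 by -0.45 (SE 0.26), and none passed over all genes. Over all genes limma called 4 higher and 1 lower, and 866 had an unadjusted p under 0.05 where chance gives 1798. These 5, named here after their values were seen, were the unnamed transcripts Gm23044 (2.10 against listed at 0), Gm10800 (7.18 against 1.79), Gm10801 (4.69 against 0.72), Gm26870 (5.20 against 1.30) and Gm24078 (listed at 0 against 1.64). The disease-associated microglia mean was 1.93 to 2.11 in the libraries labelled 5xFAD + WT HSPC and 2.70 to 2.96 in those labelled 5xFAD + 5xFAD HSPC. Of the former, libraries 1 and 2 had Thy1 against the label and libraries 2 and 3 were rich in ribosomal RNA. Without libraries 1 and 2 it differed by -0.76 and without the libraries rich in ribosomal RNA by -0.84, each with 1 library left in the WT donor arm. With the Thy1 level as a covariate it was -0.47 (adjusted p = 2.2e-12), and the choroid plexus list was at -0.09 without the libraries rich in ribosomal RNA.

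**Figure D3:**
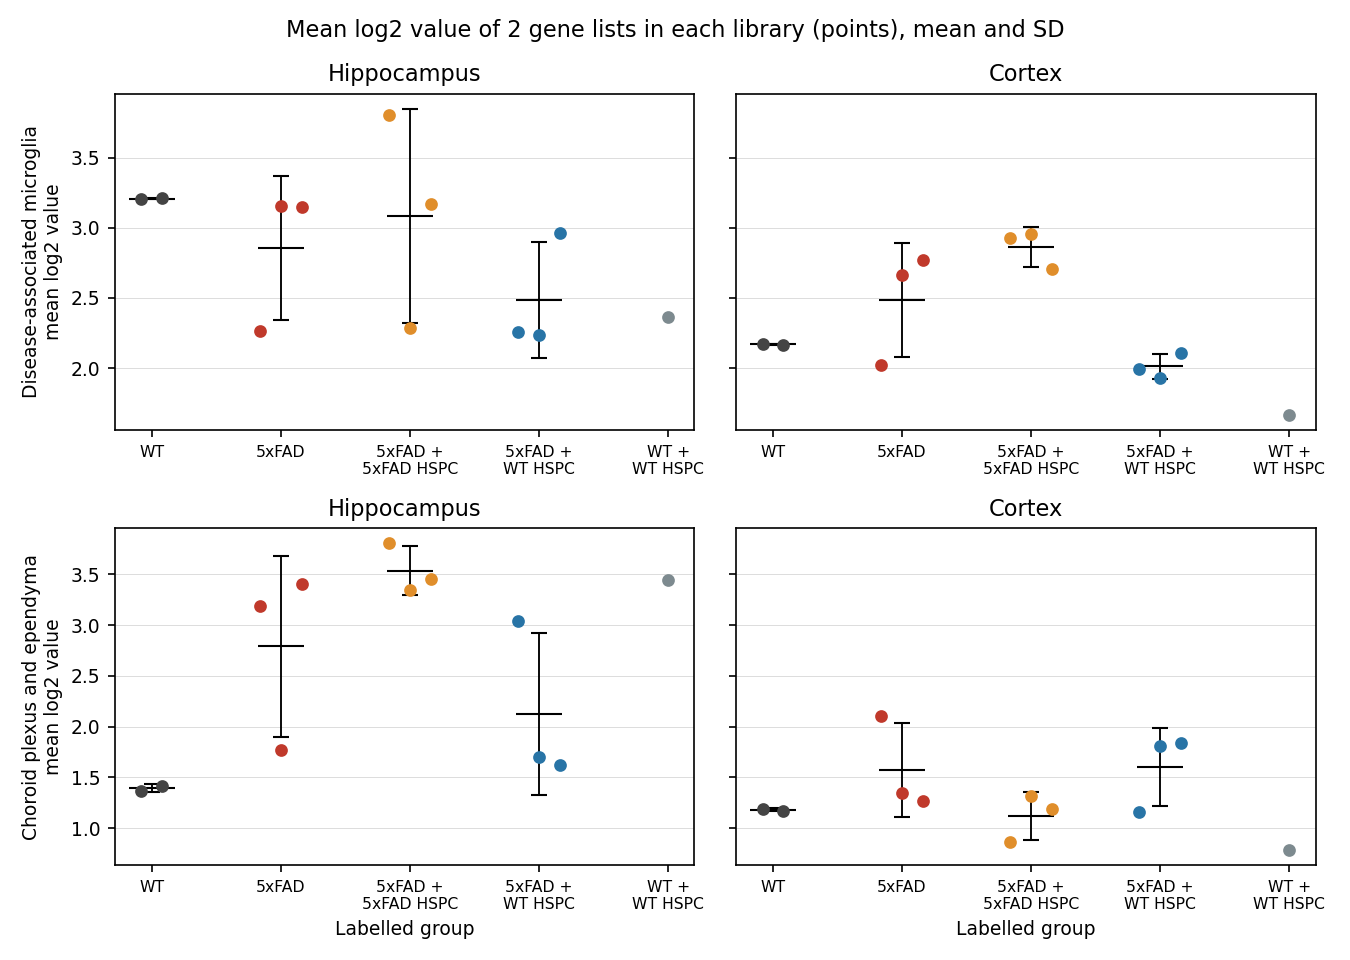
Mean log2 expression (y axis) of the disease-associated microglia list and of the choroid plexus and ependyma list in each library (points), by labelled group (x axis) and tissue, with group mean (line) and SD (bar). In cortex the 3 libraries labelled 5xFAD + WT HSPC lay at 1.93 to 2.11 for the disease-associated microglia list and the 3 labelled 5xFAD + 5xFAD HSPC at 2.70 to 2.96.

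In hippocampus, WT donors came with lower choroid plexus, meningeal and immune genes and higher synaptic genes than 5xFAD donors. Synapse genes rose in 23 of 23 members (mean 0.21, adjusted p = 7.8e-11, and 0.29 with an estimated correlation), 9 of them adjusted over the list alone. Dlg4 was at 5.79 ± 0.10 against 5.52 ± 0.09 (SD, n = 3 each), Bsn at 0.34 (SE 0.09), Syn2 at 0.38 (SE 0.10) and Gria1 at 0.36 (SE 0.11). Excitatory neuron genes rose in 12 of 12 (mean 0.31, 9 adjusted over the list alone, adjusted p = 1.9e-07, and 0.29 with an estimated correlation). Camkv was at 0.45 (SE 0.11) and Slc17a7, the vesicular glutamate transporter, at 0.53 (SE 0.14). Immediate early genes rose by a mean of 0.17 (adjusted p = 4.2e-03, and 0.35 with an estimated correlation), 1 of them, Egr4 at 0.58 (SE 0.14), adjusted over the list alone. Choroid plexus and ependyma genes fell in 15 of 15 members (mean -1.41, 12 adjusted over the list alone, adjusted p = 1.6e-10) and fibroblast and meninges genes in 11 of 12 (mean -0.72, 9 adjusted over the list alone, adjusted p = 2.1e-10). Both were at adjusted p = 0.29 with an estimated correlation. Otx2 was 1.16 ± 0.98 against 3.06 ± 0.41, Enpp2 differed by -1.78 (SE 0.56), Crabp2 by -0.77 (SE 0.15) and Fmod by -1.33 (SE 0.31). The choroid plexus mean was 3.04, 1.70 and 1.62 in libraries 1 to 3 labelled 5xFAD + WT HSPC and 3.80, 3.35 and 3.45 in those labelled 5xFAD + 5xFAD HSPC. Disease-associated microglia genes fell in 29 of 30 (mean -0.60, 1 adjusted over the list alone, adjusted p = 7.0e-07, and 0.38 with an estimated correlation). Spp1 was at -1.84 (SE 0.38), Ctsl at -0.61 (SE 0.17) and Cd63 at -0.62 (SE 0.18). The list mean was 2.26, 2.24 and 2.97 in libraries 1 to 3 labelled 5xFAD + WT HSPC, the first 2 with Thy1 against the label. It was 3.81, 2.28 and 3.17 in those labelled 5xFAD + 5xFAD HSPC, library 2 with Thy1 against the label. Without library 1 labelled 5xFAD + 5xFAD HSPC the difference was -0.24 (adjusted p = 8.0e-03), and without library 2 of that group it was -1.0002 (adjusted p = 1.1e-14). The immediate early gene call was lost without that library 1 (0.072, adjusted p = 0.12).

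Further immune lists fell in hippocampus. Among them were the MHC class II (mean -0.53, 4 adjusted over the list alone), MHC class I (-0.42), interferon response (-0.42, 2 adjusted over the list alone), complement (-0.45, 2 adjusted over the list alone) and lysosome lists (-0.38). The others were the reactive astrocyte (-0.36), inflammatory cytokine (-0.31, 1 adjusted over the list alone), homeostatic microglia (-0.28), border-associated macrophage (-0.19) and bone-marrow-derived brain macrophage lists (-0.14). These 10 had adjusted p = 1.8e-07 to 0.012, and 0.29 to 0.48 with an estimated correlation. H2-Ab1 was at -1.41 (SE 0.31), Cd74 at -1.52 (SE 0.51), Tapbp at -0.40 (SE 0.12), Rsad2 at -0.50 (SE 0.11) and the complement inhibitor Serping1 at -0.94 (SE 0.19). Lamp2 was at -0.36 (SE 0.11), P2ry12 at -0.45 (SE 0.19) and Tmem176b at -0.52 (SE 0.17). Myelin (-0.35), pericyte (-0.23), precursor (-0.19) and endothelial genes (-0.10, 1 adjusted over the list alone) fell as well, at adjusted p = 3.4e-08 to 0.027, and 0.29 to 0.39 with an estimated correlation. Ermn was at -0.43 (SE 0.13), Pdgfra at -0.18 (SE 0.05) and the junction protein Cdh5 at -0.59 (SE 0.13). The striatum and thalamus mean was 2.08, 2.92 and 1.92 in libraries 1 to 3 with WT donors and 3.19, 2.52 and 2.31 in those with 5xFAD donors, and the myelin mean was -0.16 without library 1 labelled 5xFAD + 5xFAD HSPC (adjusted p = 9.6e-06). No list member passed over all genes, where limma called 7 higher and 7 lower, all short or unnamed, and 3984 genes had an unadjusted p under 0.05 where chance gives 1811. Rps19-ps10 (0.71 ± 0.13, SD, n = 3) was listed at 0 with 5xFAD donors, and Mir6919 (2.32 ± 0.34), the immunoglobulin segment Ighv6-3 (0.48 ± 0.10) and Vmn2r-ps15 (0.45 ± 0.10) were listed at 0 with WT donors. Setting aside the libraries with Thy1 against the label left 1 library with WT donors and a disease-associated microglia mean of -0.52. The mean was -0.26 with the Thy1 level as a covariate (adjusted p = 2.6e-04). With the group names of the sample sheet the disease-associated microglia mean was -0.37 (adjusted p = 2.1e-03) and the complement call was lost (-0.23, adjusted p = 0.11). Without library 1 labelled 5xFAD + 5xFAD HSPC the MHC class I (-0.21), interferon response (-0.24), lysosome (-0.15), reactive astrocyte (-0.14) and inflammatory means (-0.12) were nearer 0 (adjusted p = 5.0e-04 to 0.038). Complement was also lost without library 1 labelled 5xFAD + 5xFAD HSPC (-0.23, adjusted p = 0.063) and homeostatic microglia without that library (-0.10, adjusted p = 0.28) or library 1 labelled 5xFAD + WT HSPC (-0.15, adjusted p = 0.092).

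The libraries labelled 5xFAD + 5xFAD HSPC and 5xFAD were compared to ask what a transplant without a change of donor genotype did. With the group names of the sample sheet every direction in this comparison turns, in both tissues. In cortex the median over expressed genes was -0.22 between them, library 1 labelled 5xFAD + 5xFAD HSPC was rich in ribosomal RNA, and changes are given less that median. Disease-associated microglia genes rose to 0.60 (25 of 30 higher before the median was taken off, adjusted p = 1.3e-23, and adjusted p = 0.18 with an estimated correlation). Itgax was at 0.96 (SE 0.26), Clec7a at 1.18 (SE 0.37), Ccl4 at 0.90 (SE 0.25) and Spp1 at 0.75 (SE 0.22). Before the median was taken off, the list mean was 0.38, and 0.15 without library 1 labelled 5xFAD (adjusted p = 3.4e-10). The inflammatory cytokine and chemokine list rose to 0.37 (11 of 16 higher, adjusted p = 2.0e-08, and adjusted p = 0.041 with an estimated correlation), and it was the one list that passed with an estimated correlation as well. Cxcl10 was at 0.68 (SE 0.16) and Ccl12 at 0.70 (SE 0.18). Complement (0.44), lysosome (0.38), MHC class II (0.37), MHC class I (0.35), interferon response (0.35), homeostatic microglia (0.33) and reactive astrocyte genes (0.28) rose at adjusted p = 1.9e-11 to 6.9e-05, and at adjusted p = 0.15 to 0.48 with an estimated correlation. C3 was at 0.55 (SE 0.07), C5ar1 at 0.57 (SE 0.11), C4b at 0.99 (SE 0.32), Cd68 at 0.87 (SE 0.29) and H2-DMb1 at 0.73 (SE 0.13). H2-D1 was at 0.64 (SE 0.22), Ifit3 at 0.61 (SE 0.21), Cx3cr1 at 0.55 (SE 0.20) and Gfap at 0.99 (SE 0.34). Choroid plexus and ependyma genes fell to -0.24 (15 of 15 lower, adjusted p = 3.7e-03, and adjusted p = 0.76 with an estimated correlation), a call lost without library 1 labelled 5xFAD (-0.19 before the median was taken off, adjusted p = 0.94) or library 2 labelled 5xFAD + 5xFAD HSPC (-0.55, adjusted p = 0.23). Adjusted over the list alone, 1 complement and 1 MHC class II gene passed and none over all genes. limma called 0 higher genes and 1 lower gene (1 and 2 with quantile normalization, 1 and 0 with median-centred libraries). The lower gene was Gm13862, named after its value was seen and listed at 0 with 5xFAD donors against 1.05 ± 0.09 (SD, n = 3). In this comparison 1176 genes had an unadjusted p under 0.05 where chance gives 1798.

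In hippocampus, fibroblast and meninges genes rose with 5xFAD donors in 12 of 12 members (mean 0.46, 1 adjusted over the list alone). Choroid plexus and ependyma (mean 0.75, 14 of 15 higher), interferon response (0.25, 19 of 20 higher), MHC class I (0.24) and disease-associated microglia genes (0.23, 28 of 30 higher) also rose. So did inflammatory cytokine (0.22, 1 adjusted over the list alone), reactive astrocyte (0.20), pericyte (0.14) and lysosome genes (0.13). These 9 lists had adjusted p = 6.7e-07 to 0.034, and 0.64 with an estimated correlation. Crabp2 was at 0.63 (SE 0.15), Islr at 0.46 (SE 0.15), Sostdc1 at 0.92 (SE 0.52), Rsad2 at 0.36 (SE 0.11) and Psmb9 at 0.64 (SE 0.29). Ctsl was at 0.35 (SE 0.17), Cxcl13 at 0.29 (SE 0.05) and Myl9 at 0.35 (SE 0.14). Synapse genes were lower in 23 of 23 members (mean -0.11), excitatory neuron genes in 11 of 12 (mean -0.15) and oxidative phosphorylation genes in 15 of 22 (mean -0.05). They had adjusted p = 2.2e-05, 0.010 and 0.034, and 0.64 with an estimated correlation. Shank3 was at -0.20 (SE 0.09), Slc17a7 at -0.26 (SE 0.14) and Ndufb8 at -0.20 (SE 0.06). No list member passed over all genes, where limma called 6 higher and 0 lower with 1883 at an unadjusted p under 0.05 and 1811 expected by chance. Among the 6 were Mir6919 (2.32 ± 0.34, SD, n = 3), Ighv6-3 (0.48 ± 0.10) and Vmn2r-ps15 (0.45 ± 0.10), each listed at 0 in the libraries labelled 5xFAD. The disease-associated microglia list turned to -0.13 without library 1 labelled 5xFAD + 5xFAD HSPC (adjusted p = 0.71) and was lost without library 1 labelled 5xFAD (-0.07, adjusted p = 0.97), while it was 0.63 without library 2 labelled 5xFAD + 5xFAD HSPC. Without library 1 labelled 5xFAD + 5xFAD HSPC the interferon response, MHC class I, inflammatory, reactive astrocyte, pericyte, lysosome, synapse and excitatory neuron calls were lost too (adjusted p = 0.15 to 0.92). The choroid plexus call was lost without library 2 labelled 5xFAD (0.24, adjusted p = 0.12).

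The libraries labelled 5xFAD + WT HSPC were last set against those labelled WT without transplant, to ask how far the treated mice differed from healthy ones. In hippocampus, microglial and immune genes were lower than in the libraries labelled WT. Disease-associated microglia genes fell in 28 of 30 members (mean -0.72, 1 adjusted over the list alone, adjusted p = 8.2e-10, and adjusted p = 0.66 with an estimated correlation). Spp1 was at 1.16 ± 0.37 (SD, n = 3) against 3.21 ± 0.01 (SD, n = 2), Cd52 at -1.12 (SE 0.52) and Ccl3 at -1.66 (SE 0.89). Interferon response (mean -0.31), lysosome (-0.36), MHC class I (-0.31), homeostatic microglia (-0.34), inflammatory cytokine (-0.31), cholesterol synthesis (-0.12), MHC class II (-0.39, 1 adjusted over the list alone), neurogenesis (-0.07) and fibroblast genes (-0.16) fell. They had adjusted p = 3.1e-07 to 0.022, and adjusted p = 0.66 to 0.70 with an estimated correlation. Ifit1 was at -0.54 (SE 0.24), Ctss at -1.07 (SE 0.59), B2m at -0.85 (SE 0.39) and P2ry12 at -0.56 (SE 0.21). Cxcl10 was at -1.17 (SE 0.47), H2-Ab1 at -1.30 (SE 0.34) and the neuroblast marker Dcx at -0.31 (SE 0.10). Myelin genes (mean 0.31, 15 of 15 higher), choroid plexus genes (0.73, 15 of 15 higher), p53 targets (0.17, 1 adjusted over the list alone) and oxidative phosphorylation genes (0.10) rose at adjusted p = 8.0e-04 to 0.022, and at adjusted p = 0.66 to 0.70 with an estimated correlation. Cnp was at 0.44 (SE 0.16), Foxj1 at 0.62 (SE 0.22), the apoptosis gene Bbc3 at 0.82 (SE 0.20) and Uqcrc1 at 0.26 (SE 0.07). No list member passed over all genes, where limma called 9 higher and 8 lower (4 and 7 with median-centred libraries), all short or unnamed. In all 3800 had an unadjusted p under 0.05 and 1811 expected by chance. n-R5s216 (2.81 ± 0.60, SD, n = 3) was listed at 0 in the libraries labelled WT, and Traj44 and Mir207 were listed at 0 in those labelled 5xFAD + WT HSPC. Thy1 went against the label in 4 of these 5 libraries, and with the Thy1 level as a covariate the disease-associated microglia mean was -0.02 (adjusted p = 0.50). The choroid plexus call was lost without library 1 labelled 5xFAD + WT HSPC (0.27, adjusted p = 0.62) or library 1 labelled WT (0.70, adjusted p = 0.11), and with all 3 WT libraries it was 0.05 (adjusted p = 0.87).

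In cortex the median over expressed genes was -0.36 in this comparison, and changes are given less that median. Immediate early genes fell to -0.44 (17 of 17 lower, adjusted p = 1.9e-03, and adjusted p = 0.84 with an estimated correlation). Egr2 was at -0.99 (SE 0.41), Fos at -0.86 (SE 0.41) and Junb at -0.83 (SE 0.42). Choroid plexus and ependyma genes rose to 0.78 (13 of 15 higher before the median was taken off, adjusted p = 7.2e-12, and adjusted p = 0.52 with an estimated correlation). Aqp1 was at 0.87 (SE 0.20) and Ttr, transthyretin, at 4.41 ± 2.06 (SD, n = 3) against 1.95 ± 0.07 (SD, n = 2). Homeostatic microglia (-0.07), myelin (-0.06), precursor (-0.08), pericyte (-0.06), astrocyte (-0.02) and cholesterol synthesis genes (-0.06) passed as lower at adjusted p = 1.8e-03 to 0.019, and adjusted p = 0.84 with an estimated correlation. All members of each list were below 0 before the median was taken off. Lysosome genes passed as lower (adjusted p = 0.014, and adjusted p = 0.84 with an estimated correlation) with a mean of -0.36, which was the median of all expressed genes. Red blood cell (0.41, mean 0.05 before the median was taken off), neutrophil (0.32, mean -0.04) and T cell genes (0.27, mean -0.09) passed as higher. They had adjusted p = 3.5e-03, 0.017 and 0.030, and adjusted p = 0.63, 0.52 and 0.84 with an estimated correlation, so that the mean and the test differed in sign for neutrophil and T cell genes. No list member passed adjusted over the list alone or over all genes. limma called 4 higher and 23 lower genes (10 and 25 with quantile normalization, 10 and 7 with median-centred libraries), with 2138 at an unadjusted p under 0.05 and 1798 expected by chance. S100a7a, a calcium-binding protein of the S100 family, was 0.27 ± 0.06 (SD, n = 3) against 1.71 ± 0.19 (SD, n = 2), a difference of -1.07 less the median (limma, adjusted p = 7.2e-03). The other 26 were short or unnamed transcripts, among them Mir7027, Mir7681, Mir6905 and Mpc1-ps, listed at 0 in the libraries labelled 5xFAD + WT HSPC. Quantile normalization ended the myelin (-0.07, adjusted p = 0.37) and homeostatic microglia (-0.06, adjusted p = 0.37) calls, and without the libraries rich in ribosomal RNA the choroid plexus list was at -0.02 (adjusted p = 0.41).

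**Figure D4:**
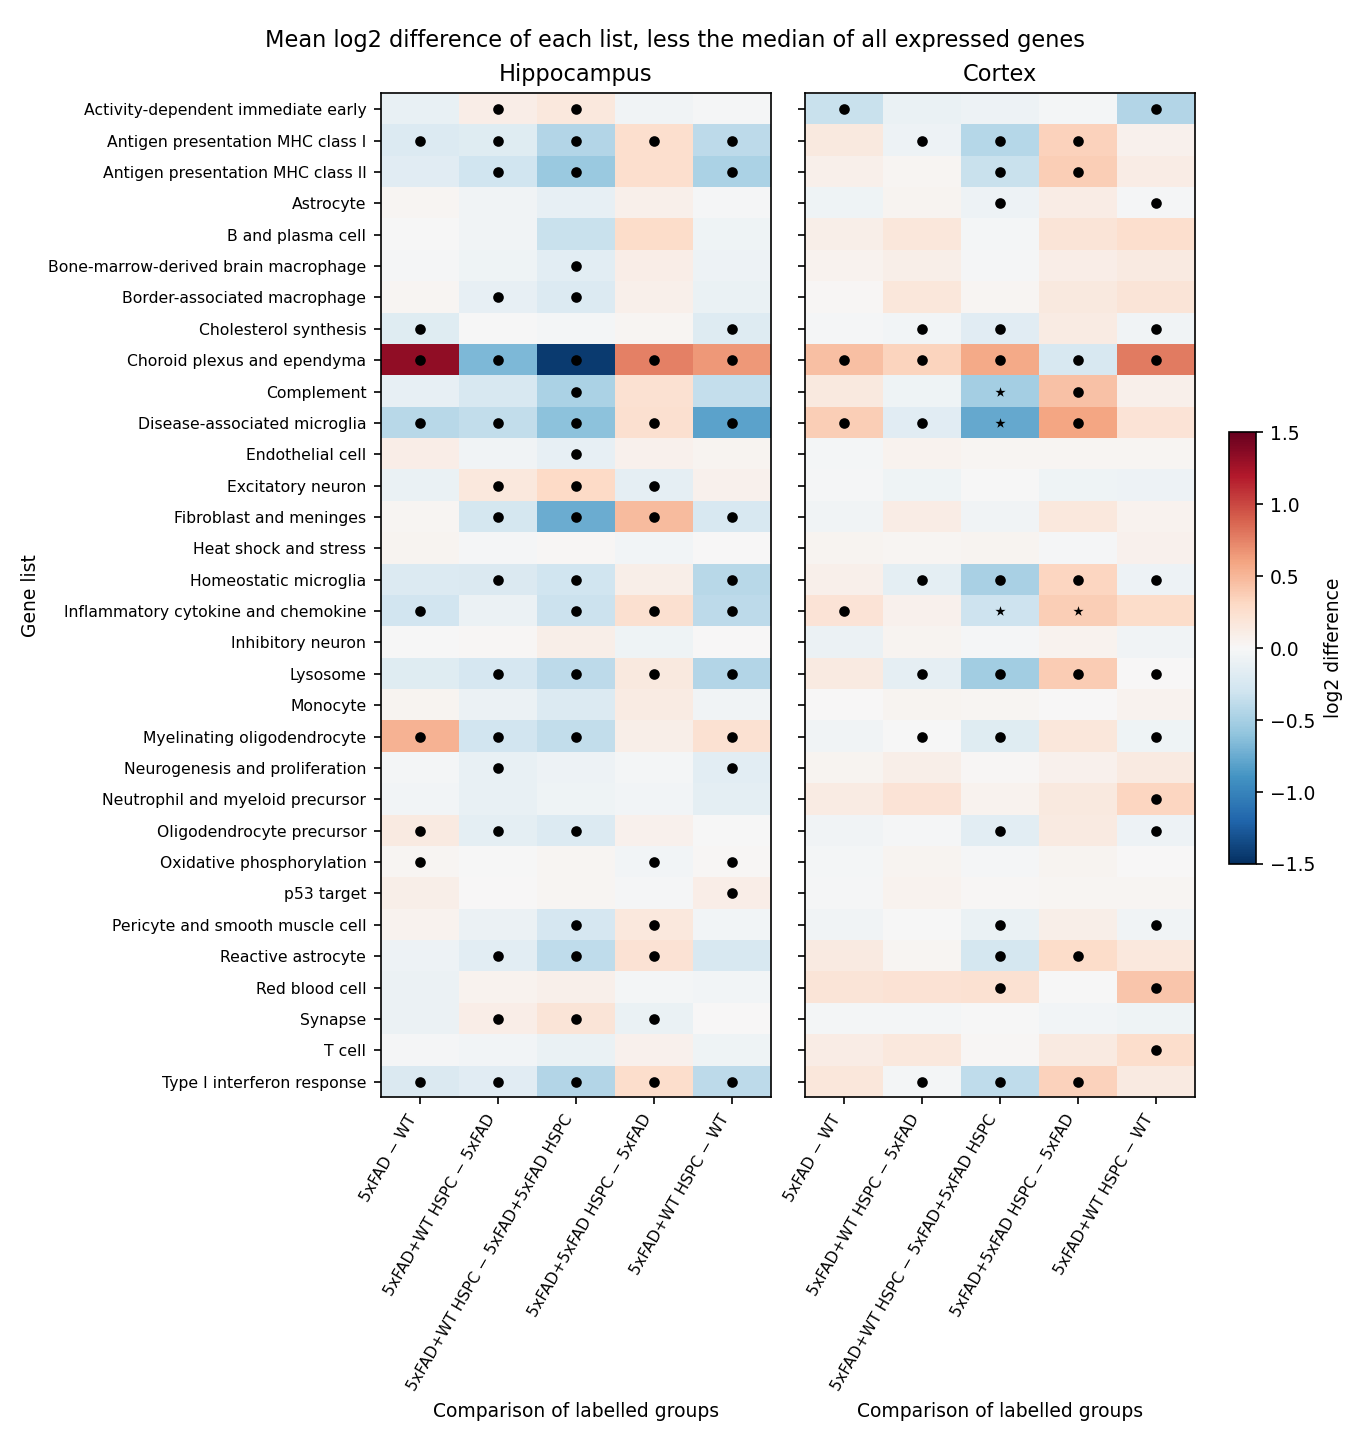
Mean log2 difference of each of the 32 gene lists less the median of all expressed genes (colour, from -1.5 to 1.5) in the 5 comparisons of labelled groups (columns) in hippocampus and cortex, with circles where the adjusted p of camera was under 0.05 with the preset correlation and stars where it was also under 0.05 with an estimated correlation. Stars stand at 3 lists in cortex between WT and 5xFAD donors and at 1 list in cortex between 5xFAD donors and no transplant.

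Effects were compared between tissues in a fit over all 24 libraries. The median over expressed genes, hippocampus minus cortex, was 0.13 for the model, 0.31 for the WT donor and 0.0998 for the donor genotype comparison. For libraries labelled 5xFAD against WT, limma called 7 genes with a larger and 5 with a smaller difference in hippocampus than in cortex, among them Ninj2 (1.29 less the median, SE 0.22, adjusted p = 0.033). In all 1661 of 38466 had an unadjusted p under 0.05 where chance gives 1923. Less the median, myelin genes differed by 0.57 and disease-associated microglia genes by -0.79 between the tissues (adjusted p = 2.5e-15 and 2.4e-08, and adjusted p = 0.70 and 0.92 with an estimated correlation). For libraries labelled 5xFAD + WT HSPC against 5xFAD, limma called 0 genes, with 1866 at an unadjusted p under 0.05. Between WT and 5xFAD donors it called 1 larger and 3 smaller (2 and 1 with quantile normalization), with 1314 at an unadjusted p under 0.05. These 4, named after their values were seen, were Mir7055 (4.08), Gm15233 (-0.49), Vmn2r-ps15 (-0.45) and Gm45911 (-0.24). Choroid plexus genes differed by -1.99 less the median in that comparison (adjusted p = 3.0e-23, and adjusted p = 0.12 with an estimated correlation), being lower with WT donors in hippocampus and higher in cortex.

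The genes called between the libraries labelled 5xFAD and WT were then tested between WT and 5xFAD donors, which share no libraries with that comparison. In hippocampus the 6 genes higher in libraries labelled 5xFAD had a mean of -0.19 with WT donors (camera, adjusted p = 0.05003 over the 4 sets), with 1 of them called lower. In cortex the 3 higher genes had a mean of -0.11 (adjusted p = 0.79), with 1 of them at a difference of 0. Neither set passed the threshold of 0.05. Of the genes lower in libraries labelled 5xFAD, 7 of 8 in hippocampus and 18 of 22 in cortex had a difference of 0 between the donors, to within 1e-08, so these sets decided nothing.

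The library labelled WT + WT HSPC stood alone in each tissue and has no replicate check. Its disease-associated microglia mean was 2.36 in hippocampus, where both libraries labelled WT were at 3.21, and 1.66 in cortex, where both were at 2.17. In cortex it was rich in ribosomal RNA.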

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

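The tests of Thy1 and of the lower disease-associated microglia list were chosen after the result was seen. Those of the cortical median and of other splits of the libraries were written before. The results given first stood out by a test of the difference between tissues (hippocampus minus cortex). None of these list differences passed with an estimated correlation (adjusted p = 0.12 to 0.99).

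Each list value is followed by that less its median given above. The last 2 comparisons had cortex libraries rich in ribosomal RNA. For libraries labelled 5xFAD against WT, 12 genes differed between the tissues, as did Thy1 and Xist of those labelled WT. Myelin (0.70, then 0.57), oligodendrocyte precursor (0.32, 0.20) and choroid plexus genes (1.003, 0.88) were higher in hippocampus than in cortex in that comparison. Disease-associated microglia (-0.67, -0.79), inflammatory cytokine (-0.37, -0.49), interferon response (-0.25, -0.38), MHC class I (-0.22, -0.34), lysosome (-0.19, -0.32) and homeostatic microglia genes (-0.15, -0.28) were lower. For WT donors against no transplant, excitatory neuron (0.53, 0.23) and synapse genes (0.44, 0.13) were higher in hippocampus, and choroid plexus (-0.69, -0.9998) and fibroblast genes (-0.067, -0.37) were lower. For WT against 5xFAD donors 4 genes differed, with excitatory neuron (0.40, 0.31), synapse (0.30, 0.20), homeostatic microglia (0.28, 0.18) and cholesterol synthesis genes (0.24, 0.14) higher and choroid plexus (-1.89, -1.99), fibroblast (-0.58, -0.68) and border-associated macrophage genes (-0.13, -0.23) lower.

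As deposited, Thy1 lay on the other side of 7 than the labelled genotype in 10 libraries, and 9 of them remained there after subtraction of each library's median deviation, which argues against library level or ribosomal RNA as the cause in those 9. Of the 9, 5 were labelled as given no WT donor cells, which argues against donor cells lowering transgene expression as the whole cause, and it stays open for the other 4. An exchange of libraries between animals may account for part of the pattern: in 3 of the 12 animals Xist against Ddx3y differed between the tissues, and these 3 were the animals with Thy1 against the label in 1 tissue. For the 3 animals against the label in both tissues a genotype other than the labelled one was not tested.

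The disease-associated microglia list was lower with WT than with 5xFAD donors in both tissues. Its mean also went with Thy1, the median deviation subtracted, whatever the label. Hippocampus libraries below 7 were at 2.24 to 2.36 and those above at 2.97 to 3.81. Cortex libraries below 7 were at 1.66 to 2.17. Those above were at 2.66 to 2.96, but for library 3 labelled 5xFAD + WT HSPC at 2.11. Without the libraries with Thy1 against the label the list difference went from -0.85 to -0.76 in cortex and from -0.60 to -0.52 in hippocampus. The hippocampus library then left with WT donors was at 2.97, those with 5xFAD donors at 3.81 and 3.17. With only library 1 labelled 5xFAD + 5xFAD HSPC left out, the hippocampus difference was -0.24. Within the cortex groups, libraries rich in ribosomal RNA differed from others by 0.061 (SE 0.11), where -2.56 was needed. This argues against ribosomal RNA as the whole cause. For library 3 with WT donors, rich and alone there above 7, it stays open. Each fit without the Thy1 libraries kept 1 library with WT donors, so its spread was assumed. Their genotype cannot be told apart from a donor effect.

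The median of all expressed genes was lower in cortex in libraries labelled 5xFAD + WT HSPC, by -0.30 against 5xFAD and -0.36 against WT. Without the libraries rich in ribosomal RNA these were -0.064 and -0.12. The second passed the bound of -0.1 that had been set against this explanation, but 1 library was left in the arm and its spread is unknown, so the bound decides nothing. Ribosomal RNA reads may thus account for most of the shift, and the donor cells stay open.

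For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In hippocampus, splits with as large a count of genes numbered 7 in the WT donor comparison (real 6, highest other 46), 2 in the donor genotype (14, 26) and 6 in the 5xFAD donor comparison (6, 17), and for lists 1 (16, 13), 1 (20, 19) and 5 (12, 18). In cortex they numbered 2 (6, 7), 2 (5, 14373) and 9 (1, 10) for genes, and 3 (8, 12), 2 (16, 17) and 7 (10, 19) for lists. The split with 14373 genes set both cortex libraries labelled 5xFAD + WT HSPC and the 1 labelled 5xFAD + 5xFAD HSPC that were rich in ribosomal RNA against the other 3, which points to a structure of the samples. Between tissues, 44 of 100 drawn splits gave at least the 4 genes of the donor genotype comparison (highest other 11788), so chance was not excluded. For the 0 genes of the WT donor comparison all 100 splits reach that count by construction (highest other 47).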

How the results depend on the processing

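The exchange of group names, the filter at a mean log2 of 1, median centring, the Thy1 covariate and the fits without doubted libraries were chosen after seeing the data, as were, for gene lists, all settings but an estimated correlation, quantile normalization and libraries left out in turn. With an estimated correlation 4 list values kept their direction and side of the threshold and 117 missed it. With quantile normalization 95 kept both and 26 missed the threshold. Under all settings added for lists 1055 kept both, 183 missed the threshold and 8 turned, and when each library was left out in turn 526 kept both, 159 missed it and 2 turned. Counts of called genes or lists moved by over 1.5 times in 45 cases and stayed within that in 45 under the planned settings, in 54 and 105 under the added ones and in 86 and 60 with libraries left out. Where 1 library was left in an arm it was assumed to vary like the other groups. Without libraries with Thy1 against the label, no hippocampus library labelled WT was left, so the model comparison and the comparison with healthy mice gave no value there. A change of pseudocount and the count-based alternatives did not apply to log2 values. Exchanging the group names as in the sample sheet turns the sign of the 5xFAD donor comparison by construction. Depth is unknown, so its limit was not measured. Some values that moved by over 1.5 times or crossed the threshold follow, and but for settings with fewer libraries or genes the cause was not tested.

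With an estimated correlation, 0 lists passed in any hippocampus comparison. In cortex 0 passed in the model comparison, the WT donor comparison and the comparison with healthy mice, while 3 passed in the donor genotype comparison and 1 in the 5xFAD donor comparison. With only the 2 groups compared, hippocampus gave 31 called genes in the model, 16 in the WT donor, 30 in the donor genotype and 3 in the 5xFAD donor comparison and 54 in that with healthy mice. Cortex gave 41 (and 7 lists), 0, 3, 0 and 83. With both tissues in 1 fit, the model and donor genotype comparisons gave 23 and 22 genes in hippocampus. In cortex the model, 5xFAD donor and healthy mouse comparisons gave 9, 0 and 15. With sex as a covariate, hippocampus gave 8 genes and 3 lists in the model, 9 genes in the donor genotype and 3 in the 5xFAD donor comparison. Cortex gave 10 in the WT donor and 8 in the 5xFAD donor comparison, and the disease-associated microglia list turned to -0.15 in the model comparison. With all 3 WT libraries, the model comparison gave 4 genes in hippocampus and 0 in cortex. The comparison with healthy mice gave 11 in hippocampus and 5 genes and 7 lists in cortex, and the test of hippocampal choroid plexus genes turned at a mean of 0.047.

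Quantile normalization gave 2 genes in the hippocampal 5xFAD donor comparison. In cortex it gave 12 genes and 2 lists in the WT donor, 9 genes in the donor genotype, 3 genes and 16 lists in the 5xFAD donor comparison and 3 lists in that with healthy mice. limma without trend and no filter each gave 2 genes in the cortical WT donor comparison. Without trend, the tests between tissues gave 6 genes for the model and 1 for the donor genotype comparison.

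Median-centred libraries gave 3, 1 and 11 genes in hippocampus in the WT donor, 5xFAD donor and healthy mouse comparisons. In cortex they gave 11 lists in the model, 10 genes and 13 lists in the WT donor, 8 genes in the donor genotype, 16 lists in the 5xFAD donor and 17 genes in the healthy mouse comparison. At a mean log2 of at least 1, hippocampus gave 3 genes in the model, 0 in the WT donor, 0 in the donor genotype, 0 in the 5xFAD donor and 6 in the healthy mouse comparison. The test of inflammatory cytokine genes in the model comparison turned at a mean of -0.036. Cortex gave 3 genes in the model, 5 lists in the WT donor, 0 genes in the 5xFAD donor, and 4 genes and 6 lists in the healthy mouse comparison. With the names exchanged, interferon response and MHC class I genes turned to 0.11 and 0.11 in the hippocampal model comparison. The WT donor and donor genotype comparisons then gave 14 and 6 genes in hippocampus, and cortex gave 11, 16 and 8 lists in the model, WT donor and donor genotype comparisons.

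With the Thy1 level as a covariate, hippocampus gave 4 genes and 3 lists in the model, 6 lists in the WT donor, 9 genes in the donor genotype, 2 genes in the 5xFAD donor and 7 genes and 2 lists in the healthy mouse comparison. Cortex gave 16 genes and 2 lists in the model comparison, where the test of disease-associated microglia genes turned at a mean of 0.017. It gave 3 genes and 2 lists in the WT donor and 0 genes in the donor genotype comparison. Without libraries with Thy1 against the label, hippocampus gave 0 genes in the 5xFAD donor comparison, and immediate early genes turned to -0.02 in the WT donor comparison. Cortex gave 43 genes and 9 lists in the model, 33 genes in the WT donor, 29 in the donor genotype, 8 in the 5xFAD donor and 50 genes and 3 lists in the healthy mouse comparison. Without the libraries rich in ribosomal RNA, cortex gave 13, 10 and 12 genes in the WT donor, donor genotype and 5xFAD donor comparisons and 16 lists in the last, and choroid plexus genes turned to -0.41 in the WT donor comparison.

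When libraries were left out in turn, hippocampus gave 26 to 40 genes in the model comparison (each of the 5 libraries moved the count by over 1.5 times, WT 1 most) and 2 (without 5xFAD 1) to 16 (without 5xFAD 2) lists, with 3 without WT 1. The WT donor comparison gave 19 to 28 genes (each of the 6 libraries) and 2 (without 5xFAD + WT HSPC 2) to 17 lists, with 10 without 5xFAD + WT HSPC 1 and 4 without 5xFAD 3. The donor genotype comparison gave 20 to 42 genes (each library but 5xFAD + WT HSPC 1, and 5xFAD + 5xFAD HSPC 3 most). The 5xFAD donor comparison gave 14 to 32 genes (each library) and 4 (without 5xFAD + 5xFAD HSPC 1) to 22 (without 5xFAD + 5xFAD HSPC 2) lists, with 5 without 5xFAD 1. There disease-associated microglia genes ranged from -0.13 to 0.63 and lysosome genes from -0.092 to 0.38, both lowest without 5xFAD + 5xFAD HSPC 1. The comparison with healthy mice gave 24 to 44 genes (each library but 5xFAD + WT HSPC 1, and WT 1 most).

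Cortex gave 25 to 46 genes and 3 to 9 lists in the model comparison, both highest without 5xFAD 1. The WT donor comparison gave 9 to 21 genes (each library but 5xFAD + WT HSPC 2) and 0 (without 5xFAD 3) to 10 lists, with 5 without 5xFAD + WT HSPC 1 and 5 without 5xFAD + WT HSPC 2. The donor genotype comparison gave 9 to 35 genes (each library, 5xFAD + 5xFAD HSPC 1 most), and the 5xFAD donor comparison 8 to 15 (each library). The comparison with healthy mice gave 24 to 43 genes (without 5xFAD + WT HSPC 3) and 2 (without WT 2) to 11 lists, with 5 without 5xFAD + WT HSPC 1 and 6 without WT 1. Between tissues the model comparison gave 13 to 84 genes (84 without hippocampus WT 1, 48 without WT 2, 20 and 21 without 5xFAD 1 and 2, and 33 and 22 without cortex WT 1 and 2). The WT donor comparison gave 0 to 10 (0 only without cortex 5xFAD + WT HSPC 2). The donor genotype comparison gave 2 (without cortex 5xFAD + WT HSPC 2) to 15 (without hippocampus 5xFAD + WT HSPC 1 or cortex 5xFAD + 5xFAD HSPC 1), with 8 to 14 without any other hippocampus library of that comparison.

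For the genes called in the model comparison, the mean of the higher hippocampus genes with WT against 5xFAD donors was past 0.05 before adjustment over the 4 sets. It was -0.11 with genes at adjusted p under 0.1 and -0.023 with the 200 smallest p, both no longer past it, and -0.26 to -0.11 with libraries left out. The lower hippocampus genes passed at 0.088 with the 200 smallest p. Of the lower genes called, 7 of 8 and 18 of 22 had a difference of 0, so those sets decide nothing. The lower cortex genes ranged from -0.025 to -0.010 and passed without 5xFAD + WT HSPC 1 or 5xFAD + 5xFAD HSPC 1.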

Other observations

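Markers of blood-derived cells were read for the donor contribution, since HSPCs give rise to monocytes, macrophages and lymphocytes. Ccr2, a chemokine receptor of monocytes, differed by -0.03 in hippocampus between libraries labelled 5xFAD + WT HSPC and 5xFAD, and Ms4a7, expressed by bone-marrow-derived brain macrophages, by -0.02. The macrophage list had means of -0.06 in hippocampus (limma camera, adjusted p = 0.30) and, less the median, 0.09 in cortex (adjusted p = 0.42), and the monocyte list -0.08 (adjusted p = 0.48) and 0.04 (adjusted p = 0.39). With WT against 5xFAD donors the B and plasma cell list had a mean of -0.32 in hippocampus (adjusted p = 0.084), with the immunoglobulin genes Igkc at -1.94 (SE 0.66) and Ighm at -0.70 (SE 0.37). Monocyte, B and plasma cell, inhibitory neuron and heat shock genes passed in none of the 5 comparisons of either tissue, and inhibitory neuron and heat shock genes had means of 0.10 (adjusted p = 0.15) and 0.04 (adjusted p = 0.22) with WT against 5xFAD donors in hippocampus.

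Gm10800 and Gm26870, unnamed transcripts chosen after their values were seen, were called higher with WT than with 5xFAD donors in both tissues. Gm10800 was 6.74 ± 0.59 against 2.41 ± 0.45 in hippocampus (SD, n = 3 each) and 7.18 ± 0.79 against 1.79 ± 0.46 in cortex. Gm26870 was 4.76 ± 0.59 against 1.97 ± 0.41 and 5.20 ± 0.80 against 1.30 ± 0.12.

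Markers of the dissected region varied between libraries of 1 group. Ttr, a choroid plexus product, was 7.40, 3.68 and 7.78 in hippocampus libraries 1 to 3 labelled 5xFAD and 2.49 and 2.28 in those labelled WT. Striatum and thalamus markers had hippocampus means of 3.61, 3.19 and 2.92 in libraries 5xFAD 1, 5xFAD + 5xFAD HSPC 1 and 5xFAD + WT HSPC 2. The other 9 were at 1.92 to 2.52. Hippocampus markers had means of 2.98 to 3.43 in hippocampus and 1.341 to 1.997 in cortex. The mean RNA concentration was 956 ng per microlitre in hippocampus and 120 in cortex in libraries labelled WT, and 283 and 1029 in those labelled 5xFAD + WT HSPC.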
